A study of Mus musculus with 5 samples.

How the data were processed

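DNA methylation was measured by reduced representation bisulfite sequencing (RRBS) in 5 libraries of mouse embryonic stem (ES) cells, 1 library for each genotype. Per the labels' protocols, genomic DNA was cut with MspI, which recognises CCGG whatever the methylation of its CpG, ligated to a methylated adapter, converted with bisulfite, amplified by PCR and sequenced on an Illumina HiSeq. Bisulfite turns unmethylated cytosine into uracil and leaves 5-methylcytosine intact, so that a cytosine still read as C counts as methylated. Cutting at CCGG enriches CpG-rich DNA, and the values describe the MspI fragments assigned to each gene rather than the whole gene. Where these fragments lie is not known, so the level of a row need not be that of a promoter. Bowtie2 2.1.0 and the mouse build mm9 are named in the submitters' processing notes. The methylation caller, any coverage filter, the interval around each gene and the cytosine context (CpG or other) are not given in the sources used here.

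The deposited table has 31472 rows, each named for a gene, and 1 column per library. Per the file headers, each cell pairs a count of 5mC calls with a count of C calls, as whole numbers that the authors had not scaled to depth. The second number was read as the unmethylated count and not as the total, because the first number exceeded it in 20851 cells. The analysis had been planned for counts or fractions per site, and the paired counts were used in their place with the tests planned for methylated and unmethylated counts. Column names matched the sample descriptions in the labels, which gave each library its genotype. Of the row names, 26294 (83.5%) equalled a symbol and a further 2474 equalled a synonym in a RefSeq table for GRCm38.p6, which was used for names only. The rows carry no positions, and no coordinates are given. Rows of overlapping or neighbouring genes may hold the same calls.

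The methylation level of a row was 100 times its methylated calls divided by its methylated plus unmethylated calls. Rows with at least 10 calls in all 5 libraries entered the comparisons (25673 rows, 81.6%). Levels were averaged over rows with equal weight. The SD over rows describes the spread between genes and is not a replicate error. The share of the level in the unrecombined control that was left in each knockout was computed over the 15109 rows with at least 50% methylation in that control. A change of at least 25 percentage points was counted as a fall or a rise. Exact (Clopper-Pearson) 95% intervals were computed from the calls. For a row without methylated calls, the upper limit was set at 3 counts of its calls, which is 30% at 10 calls and 3% at 100 calls. Neighbouring cytosines on a read and PCR copies of a fragment are not independent, so intervals and limits cover counting error only. Fisher's exact test (two-sided) per row with Benjamini-Hochberg adjustment at 0.05 compared pairs of libraries, not conditions.

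Gene lists were fixed in advance. The imprinted genes were listed for differentially methylated regions, the germline genes for methylated promoters and the housekeeping genes for promoters in CpG islands (CpG-rich stretches). Of the imprinted genes named, 27 of 32 were measured at 10 or more calls in every library, with 25 of 32 germline genes, 13 of 13 pluripotency genes, 14 of 15 marker genes of other cell types, 9 of 12 housekeeping genes, 13 of 17 genes of the methylation and silencing machinery and 3 of 10 genes of the 2-cell stage. The names of endogenous retroviruses, LINE-1, SINE and satellite families matched 0 rows, so repeats were not analysed here. A list's median level was placed among 10000 random lists of the same size, matched on the level in the control in 20 bins. A percentile below 2.5 or above 97.5 was taken as outside the random range. Such percentiles describe these libraries. They treat rows as exchangeable, which neighbouring genes are not.

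The genes named singly followed a rule written in advance. It took the 5 members of each list with the largest absolute change from control to double knockout, of which 1 housekeeping gene is not reported here. For each conditional knockout it took the 5 rows with the largest and the 5 with the smallest fall among rows with at least 50% in the control, and for the triple knockout the 5 highest such rows. For each pair of conditional knockouts it took the 5 rows with the largest difference each way. Many rows taken by the last parts rested on few calls. A second ranking, chosen after the data were seen, used the 7726 rows with at least 100 calls in every library and an even depth share. The depth share of a row is its calls divided by the library's median calls per row, and it was called even when it lay within 1.5-fold over the 5 libraries.

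Alternatives set before the data were examined were minimums of 5 and 20 calls, medians or pooled calls in place of means, rows of each library alone, subtraction of the triple knockout level, control minimums of 20% and 80%, size rules of 10 and 50 points, and random lists matched in 5 bins or unmatched. Alternatives added after the data were seen restricted rows to even depth share (within 1.5-fold over the 5 libraries, or within 1.25-fold in the pair compared, called near-equal), used deep and even rows, matched random lists on depth in 5 classes, and kept 1 row per imprinted cluster. Unrecombined cells in the Dnmt1 cKO culture would have been excluded if more than 5% of deep and even rows, at 50% or more in the control, had an upper limit in Dnmt1 cKO below the level those cells alone would leave. This held for 6 of 3289 rows, which decides little, because the share of such cells was derived from the mean difference itself. An earlier form of this count was written before its result was seen, but it used fewer rows and a share that was derived wrongly and was too small. The corrected count and the comparison over imprinted genes were chosen after the data were seen. The tests were tried on simulated calls drawn at the real depths of 25673 rows. Each call was drawn independently, so correlated calls and unequal coverage of fragments were not simulated. Fisher's test called 61%, 60% and 57% of 100 rows raised by 20 points for double cKO against Np95 cKO, double cKO against Dnmt1 cKO and Dnmt1 cKO against Np95 cKO. At 40 points it called 85%, 80% and 89%. Of rows without a simulated change, 0.0196%, 0.0196% and 0.0118% were called, and 0.322%, 0.565% and 0.565% passed the 25-point rule in either direction. Of 60 unchanged random lists of 27 rows in Dnmt1 cKO, 6.67% fell outside the random range, and 90% of lists lowered by 40% fell below it. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.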

Results

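RRBS profiles were compared between mouse ES cells of 5 genotypes to ask how much DNA methylation was left after loss of NP95, of DNMT1 or of both. NP95 (also called UHRF1) binds hemimethylated DNA and recruits DNMT1, the enzyme that copies methylation onto newly made DNA. Cells of C57BL/6 background carried floxed alleles of Np95, Dnmt1 or both genes and a CreERT2 transgene, whose recombinase is switched on by 4-hydroxytamoxifen (4-OHT). Np95 cKO, Dnmt1 cKO and Np95 Dnmt1 double cKO cells were collected at day 6 with 4-OHT. The control was the Dnmt1 floxed line at day 0 without 4-OHT (Dnmt1 wt). Dnmt triple knockout cells (TKO), which lack the DNA methyltransferases, gave the background of the assay.

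Each group had 1 library, so no difference reported here has a replicate check. The starting levels of the Np95 and double floxed lines and of the parent of TKO were not measured. Against the control, genotype in these libraries cannot be separated from cell line. The control was untreated and collected before the conditional knockouts, and no treated line without floxed alleles was measured. In each conditional knockout, Dnmt1 cKO included, genotype thus cannot be separated from treatment and time in culture. Methylation at a targeted gene does not test its deletion, and Np95 itself was not analysed here. The Dnmt1 row was at 82.8% (95% interval 77.4 to 87.3, 238 calls) in Dnmt1 wt and 20.9% (14.7 to 28.4, 148 calls) in Dnmt1 cKO. Total calls were 8715561 in Dnmt1 wt, 9829718 in Np95 cKO, 5793886 in Dnmt1 cKO, 9490563 in double cKO and 6512338 in TKO. The median row held 138, 161, 104, 165 and 123 calls in these libraries.

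Methylation was lower in each knockout than in Dnmt1 wt. The mean level over rows was 56.1% (SD over rows 31.6) in Dnmt1 wt, 13.1% (9.28) in Np95 cKO, 20.7% (13.6) in Dnmt1 cKO, 16.7% (11.1) in double cKO and 2.81% (2.73) in TKO. Among the 15109 rows with at least 50% in Dnmt1 wt, the mean went from 80.2% to 18.5% in Np95 cKO, 28.6% in Dnmt1 cKO and 23.0% in double cKO, against 3.43% in TKO. Np95 cKO cells thus kept 23.1% of the control level, Dnmt1 cKO cells 35.6% and double cKO cells 28.7%, with 4.28% left in TKO. Pooled over the calls of all 31472 rows, the level was 35.4% (35.4 to 35.5) in Dnmt1 wt, 8.67% (8.65 to 8.69) in Np95 cKO, 14.8% (14.8 to 14.8) in Dnmt1 cKO, 11.8% (11.7 to 11.8) in double cKO and 2.32% (2.31 to 2.33) in TKO. Rows with at least 50% methylation numbered 15109 in Dnmt1 wt, 30 in Np95 cKO, 586 in Dnmt1 cKO, 129 in double cKO and 1 in TKO.

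**Figure D1:**
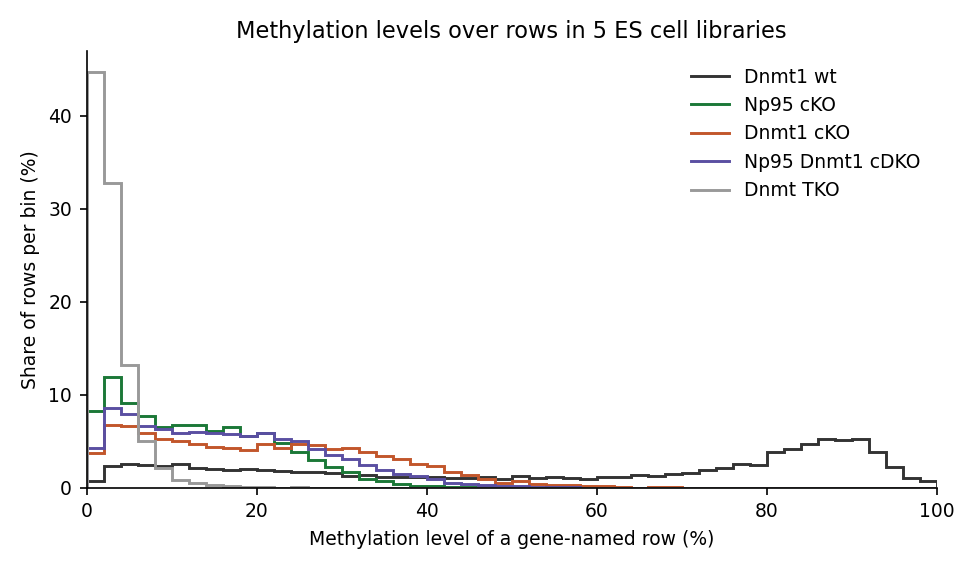
Share of the 25673 rows (y axis, % per bin) at each methylation level (x axis, %) in 5 libraries, 1 line per library. Dnmt1 wt has a median of 65.6%, the medians of Np95 cKO, double cKO and Dnmt1 cKO lie at 11.9%, 15.4% and 19.4%, and that of TKO at 2.22%.

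By the 25-point rule, 17594 rows fell in Np95 cKO, 16266 in Dnmt1 cKO, 16909 in double cKO and 18664 in TKO, and 10, 41, 26 and 0 rows rose. Of the rows at 50% or more in Dnmt1 wt, 99.8% fell in Np95 cKO, 98.1% in Dnmt1 cKO, 99.4% in double cKO and 99.99% in TKO. Fisher's exact test between the libraries put 24451 rows lower and 52 higher in Np95 cKO, 22400 lower and 157 higher in Dnmt1 cKO, 23749 lower and 106 higher in double cKO, and 24662 lower and 4 higher in TKO. Of the 77 rises in the conditional knockouts, 75 were in rows whose share of the library's depth was at most 0.5 of that in the control. Among rows of near-equal depth share in both libraries, 0 rose in Np95 cKO, 1 in Dnmt1 cKO and 0 in double cKO.

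The mean level left in each conditional knockout rose with the level of the rows in Dnmt1 wt, called their starting level here. For Np95 cKO and double cKO this is the level of another line. Rows between 80% and 90% in Dnmt1 wt averaged 19.8% in Np95 cKO, 30.6% in Dnmt1 cKO, 24.7% in double cKO and 3.56% in TKO. Rows between 20% and 30% averaged 6.14%, 10.7%, 8.87% and 2.02%. The share kept in Dnmt1 cKO was 42.9% for rows at 20% to 30% in the control and 35.7% for rows at 80% to 90%, and in Np95 cKO it was 24.7% and 23.1%. TKO read 8.13% and 4.16% of the control level in these bins. This background was not subtracted and adds more to the shares of low rows. The shares alone thus do not show that rows of low starting level kept more. Rows at 5% or less in Dnmt1 wt (1117 rows) were at 3.21% in the control, 1.80% in Np95 cKO, 2.99% in Dnmt1 cKO, 2.38% in double cKO and 1.27% in TKO.

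**Figure D2:**
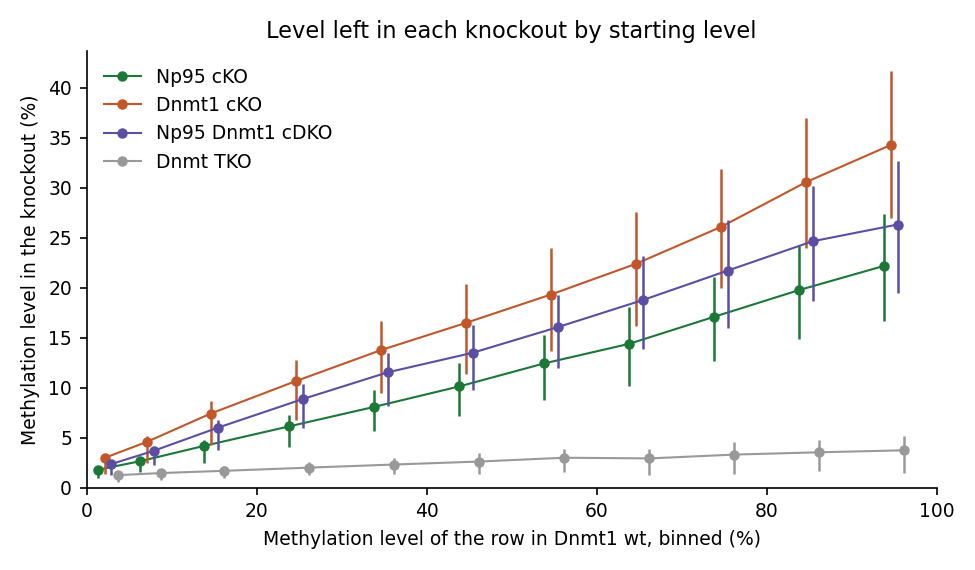
Mean methylation level in each knockout (y axis, %) for rows grouped by their level in Dnmt1 wt (x axis, %), with points at bin means, shifted slightly sideways by library, and vertical bars from the 25th to the 75th percentile of rows. Dnmt1 cKO lies above double cKO and double cKO above Np95 cKO in each bin, for example 30.6%, 24.7% and 19.8% in rows at 80% to 90% in the control.

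Imprinted genes, which are expressed from a single parental allele, kept less methylation in Dnmt1 cKO and double cKO than other rows of the same starting level. Their median (27 genes) was 36.4% in Dnmt1 wt, 5.85% in Np95 cKO, 7.26% in Dnmt1 cKO, 6.24% in double cKO and 1.69% in TKO. Matched random lists had medians of 7.28% in Np95 cKO, 12.2% in Dnmt1 cKO and 10.3% in double cKO, and 595, 5 and 2 of 10000 such lists were as low. The imprinted median thus lay below the random range in Dnmt1 cKO and double cKO and inside it in Np95 cKO. By the 25-point rule 17 members fell in Np95 cKO, 15 in Dnmt1 cKO, 14 in double cKO and 19 in TKO, and 0 rose. Mest, a maternally imprinted gene of the mesoderm, went from 70.9% (65.0 to 76.3, 261 calls) to 15.3% (11.8 to 19.5) in Np95 cKO, 15.9% (11.4 to 21.3) in Dnmt1 cKO and 13.9% (10.8 to 17.6) in double cKO. Nespas, antisense in the Gnas cluster, went from 53.5% (50.4 to 56.5, 1058 calls) to 8.17%, 4.85% and 5.62%. Peg13 was at 59.2% in Dnmt1 wt, 22.0% (18.2 to 26.2) in Np95 cKO, 14.7% (10.5 to 19.8) in Dnmt1 cKO and 7.96% (5.66 to 10.8) in double cKO. Cdh15, a muscle cadherin gene, went from 80.7% to 14.7%, 34.9% and 15.4%. Snrpn went from 85.0% (40 calls) to 38.5% (13.9 to 68.4, 13 calls) in Dnmt1 cKO and 21.1% (38 calls) in double cKO. In Np95 cKO 0 of its 26 calls were methylated, which allows up to 11.5%. The row with the most methylation left in double cKO, Impact, rested on 22 calls there and is named after its value was seen (40.9%, against 29.9% in Dnmt1 wt). In Dnmt1 cKO 26 of the 27 members lay below the control. The exception was Blcap, at 35.7% (28.5 to 43.3, 171 calls) there and 33.8% (784 calls) in Dnmt1 wt.

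Germline genes, many of which are silenced by promoter methylation outside germ cells, had been listed for methylated promoters. Their high level in the control was thus part of the choice and is not a result. Their median (25 genes) was 73.4% in Dnmt1 wt, 13.2% in Np95 cKO, 21.3% in Dnmt1 cKO, 14.6% in double cKO and 3.50% in TKO. Of 10000 matched random lists, 974 were as low in Np95 cKO, 1231 in Dnmt1 cKO and 37 in double cKO, where the random median was 19.5%. The list thus lay outside the random range in double cKO alone. No allowance was made for placing 7 lists in 3 conditional knockouts, so this single placement is weak. By the 25-point rule 24 members fell in Np95 cKO, 23 in Dnmt1 cKO, 23 in double cKO and 25 in TKO. Asz1, needed for piRNA production in the testis, went from 84.5% (78.7 to 89.2, 200 calls) to 8.92% (6.06 to 12.6) in Np95 cKO, 15.2% (9.76 to 22.1) in Dnmt1 cKO and 9.01% (6.25 to 12.5) in double cKO. Tuba3b, a testis tubulin gene, was at 93.4% in Dnmt1 wt, 20.4% in Np95 cKO, 35.2% in Dnmt1 cKO and 19.8% in double cKO, and its neighbour in name Tuba3a at 87.0%, 24.9%, 24.9% and 18.5%. The near-identical tubulin copies may share calls. Syce1, a component of the synaptonemal complex, was at 86.8%, 24.1%, 25.6% and 17.6%. Rhox6, a homeobox gene of the X chromosome, was at 78.9% in Dnmt1 wt and at 5.97% (3.97 to 8.57), 7.09% (3.45 to 12.7) and 9.47% (6.09 to 13.9) in the conditional knockouts, values whose intervals overlap that of TKO (8.79%, 5.11 to 13.9).

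The other lists lay inside the random range in the conditional knockouts. Pluripotency genes (13) had a median of 28.0% in Dnmt1 wt, 5.80% in Np95 cKO, 8.64% in Dnmt1 cKO and 8.18% in double cKO, and 7, 4 and 4 members fell by the size rule. Nanog, a core pluripotency factor, went from 82.9% (73.0 to 90.3, 82 calls) to 10.2%, 18.8% and 9.38%. Esrrb, an orphan nuclear receptor of naive ES cells, went from 84.7% to 16.3% (12.5 to 20.6) in Np95 cKO, 24.8% (19 to 31.2) in Dnmt1 cKO and 31.6% (26.1 to 37.5) in double cKO. Tfcp2l1 was at 35.2%, 8.88%, 24.7% and 13.1%, Zfp42 at 46.8%, 12.3%, 11.8% and 13.8%, and Dppa5a at 41.4%, 6.77%, 4.96% and 8.18% in Dnmt1 wt, Np95 cKO, Dnmt1 cKO and double cKO.

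Genes of the methylation and silencing machinery (13) had a median of 13.7% in Dnmt1 wt and 4.74%, 8.89% and 5.29% in Np95 cKO, Dnmt1 cKO and double cKO, with 5 members falling in each. Zfp809, a zinc finger protein that recruits silencing to proviruses, went from 60.3% to 7.25% (5.16 to 9.86), 21.0% (15.8 to 26.9) and 15.8% (12.8 to 19.2). Dnmt3l, a cofactor of de novo methylation, went from 46.5% to 10%, 13.7% and 17.1%, and Morc1, which silences transposons in the male germline, from 88.0% to 20%, 8.89% and 14.8%. Tet3, a 5-methylcytosine oxidase, was at 82.8% in Dnmt1 wt and 10.3%, 42.9% and 37.0% in the conditional knockouts. Its depth was uneven, with 29 calls in Dnmt1 wt, 232 in Np95 cKO, 14 in Dnmt1 cKO and 27 in double cKO.

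Marker genes of trophoblast, fibroblasts and early lineages (14) had a median of 18.9% in Dnmt1 wt and 5.21%, 8.35% and 7.03% in the 3 conditional knockouts, with 4 members falling in each. Elf5, a trophoblast regulator held silent by methylation in ES cells, went from 76.7% (57.7 to 90.1, 30 calls) to 25%, 38.5% and 22.9%. Its level in Dnmt1 cKO rested on 13 calls (13.9 to 68.4). Hand1 went from 48.6% to 7.35% (5.69 to 9.31), 16.4% (13.2 to 19.9) and 15.2% (12.8 to 17.8), Thy1 from 65.2% to 14.0%, 13.8% and 18.1%, and Gata4 from 32.2% to 7.24%, 9.37% and 9.69%. Col1a2 was at 89.5% on 19 calls in the control and at 13%, 26.7% and 9.09%. Housekeeping genes (9) had a median of 24.1% in Dnmt1 wt and 6.82%, 10% and 9.74%, and 3, 2 and 3 members fell. Tbp went from 86.4% to 23.3%, 13% and 16.3%, and Hprt was at 39.3%, then 6.82%, 18.3% and 6.67%. Gapdh was at 24.1%, 3.33%, 9.3% and 6.57%, and Ppia at 23.1%, 2.95%, 6.5% and 7.1%. The 3 measured genes of the 2-cell stage fell in each conditional knockout. Gm12794 went from 87.8% to 9.68%, 11.4% and 27.1%, Tcstv3 from 81.2% (16 calls) to 16.7%, 44.4% and 32.0%, and Zfp352 from 58.6% to 15.6%, 22.0% and 19.9%.

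**Figure D3:**
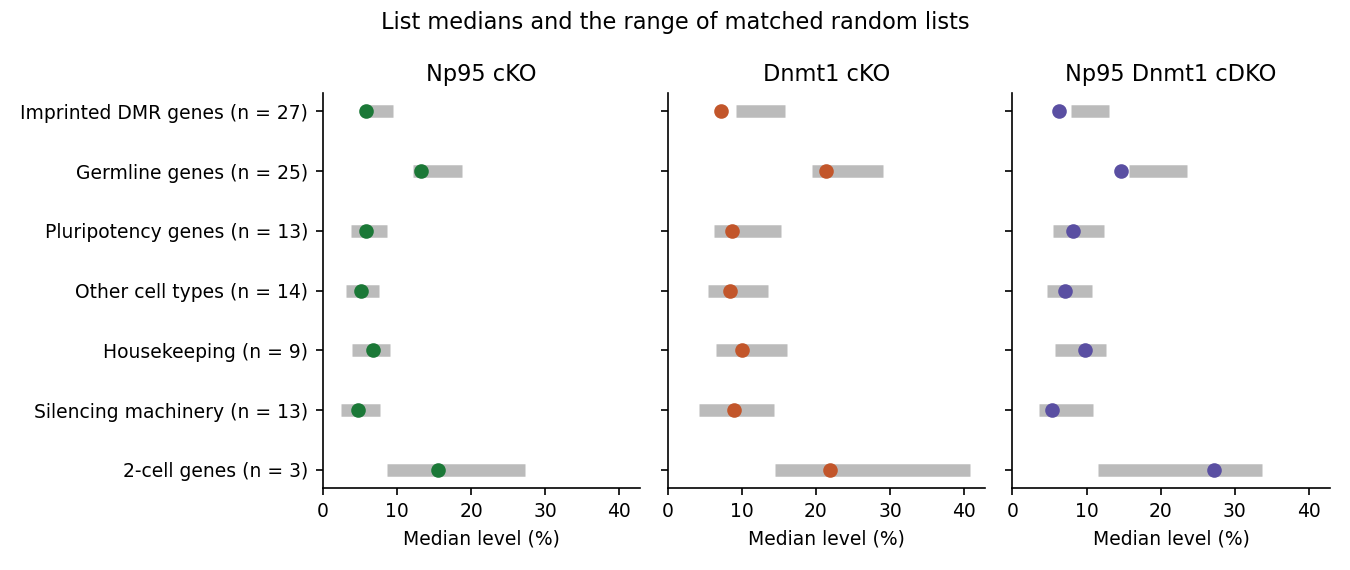
Median methylation level (x axis, %) of 7 gene lists (rows) in the 3 conditional knockouts (panels), as points, with grey bars spanning the central 95% of 10000 random lists matched on the level in Dnmt1 wt. Points left of their bars are the imprinted genes in Dnmt1 cKO (7.26%) and double cKO (6.24%) and the germline genes in double cKO (14.6%).

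Rows with the largest and smallest losses mostly had few calls. The largest falls in Np95 cKO were in 1700065O20Rik, Gm19512, LOC100862256 and the olfactory receptor genes Olfr766 and Olfr981, each at 100% in Dnmt1 wt and 0% in Np95 cKO on 10 to 18 calls in these libraries, where 12 calls allow up to 25%. In Dnmt1 cKO the largest falls were in Pacs1, Gm18593, Mir686, Gm5326 and Atg9b, and in double cKO in Mir686, Itih5l-ps, Gm19682, Gm19253 and Gm6621. Mir686 went from 100% (33 calls) to 2.34% (385 calls) in Np95 cKO, 3.36% (238 calls) in Dnmt1 cKO and 3.12% (384 calls) in double cKO, with a depth that differed widely from the control. The smallest falls in Np95 cKO were in Phrf1, Pramel7, Gm19118, Olfr671 and Gm18428. Phrf1 was at 57.4% (44.8 to 69.3) in Dnmt1 wt, 45.9% (29.5 to 63.1) in Np95 cKO and 26.3% (9.15 to 51.2) in TKO. The same ranking, which ends in the smallest falls or the largest rises, gave Tas2r117, Zfp616, Zfp672, Gm6618 and Gm18878 in Dnmt1 cKO, where the levels of the first 4 lay above the control, and in double cKO Gm13875, which lay above it, Gm12692, Taar7f, Rps15-ps2 and Gm7118. Gm6618 was at 52.1% (40 to 63.9) in Dnmt1 wt, 54.1% (36.9 to 70.5) in Dnmt1 cKO, 3.12% in Np95 cKO and 19.09% in double cKO.

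Among the 3289 deep and even rows with at least 50% in Dnmt1 wt, a ranking chosen after the data were seen, the smallest fall in Dnmt1 cKO was in Rtn3, a reticulon of the endoplasmic reticulum. It was at 64.3% (56.7 to 71.5, 171 calls) in Dnmt1 wt, 54.1% (45.3 to 62.7, 135 calls) in Dnmt1 cKO, 35.3% (29.2 to 41.7) in double cKO and 21.1% (16.1 to 26.7) in Np95 cKO. Unc93b1, which carries Toll-like receptors to endosomes, was at 51.1% in Dnmt1 wt, 38.1% (29.4 to 47.5) in Dnmt1 cKO and 27.9% (21.3 to 35.2) in Np95 cKO, the smallest fall there. In double cKO the smallest fall was in Cd59a, an inhibitor of complement, from 52.8% (46.2 to 59.4) to 35.9% (29.9 to 42.1). At the other end, Myl10, a myosin light chain gene, went from 96.1% to 14.7% (9.33 to 21.6) in Np95 cKO, and Dennd1c, an activator of Rab proteins, from 94.3% to 19.13% (14.3 to 24.8) in Dnmt1 cKO.

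The design next asked whether loss of both proteins left less methylation than loss of either. Double cKO did not have the lowest levels. Its mean was 3.55 points above that of Np95 cKO (SD over rows 7.52, median 2.65), with 75.7% of rows higher, and its mean minus that of Dnmt1 cKO was −3.96 points (SD over rows 9.15, median −2.40), with 69.2% of rows lower. The order Np95 cKO, double cKO, Dnmt1 cKO from low to high held in 12369 rows (48.2%). The order Np95 cKO, Dnmt1 cKO, double cKO held in 20.7%, and double cKO was the lowest in 17.0% with Np95 cKO next and in 3.63% with Dnmt1 cKO next. By the size rule 315 rows were higher and 53 lower in double cKO than in Np95 cKO, and 117 were higher and 647 lower than in Dnmt1 cKO. Simulated rows without a change gave 39 higher and 43 lower for the first pair and 69 higher and 75 lower for the second. The simulation gave both libraries equal levels and drew each call independently. Correlated calls and unequal coverage of fragments were left out, so its counts may be too low. Fisher's exact test between the libraries put 3972 rows higher and 425 lower than in Np95 cKO, and 356 higher and 2892 lower than in Dnmt1 cKO.

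Rows far higher in double cKO than in Np95 cKO included Errfi1, a feedback inhibitor of EGF receptor signalling, at 59.4% (50.9 to 67.6, 143 calls) against 4.51% (2.60 to 7.22, 355 calls), with 50.4% (41.4 to 59.4) in Dnmt1 cKO and 96.0% in Dnmt1 wt. Taar7f, Atpaf1, Samd15 and Tmem194b completed this group on 14 to 17 calls in double cKO. Rows far lower than in Np95 cKO were Gm4528, Pramel7, Gm18591, Gm11980 and Gm19231, with 10 to 19 calls in Np95 cKO. Against Dnmt1 cKO, the highest rows were Samd15, Gm7512, Setd2, Gm13875 and Igkv5-48, and the lowest were Gm18555, Cox11, Zfp616, Gm6621 and 4930426I24Rik. Setd2, a histone methyltransferase gene, was at 48.4% (30.2 to 66.9, 31 calls) in double cKO and 1.36% (0.165 to 4.83, 147 calls) in Dnmt1 cKO. Calls of these rows often differed widely between the libraries compared. Samd15 had 16 calls in double cKO, 838 in Np95 cKO and 549 in Dnmt1 cKO. Whether the same fragments were covered was not tested, so these are not firm differences between genotypes. Among deep and even rows, Cd59a was at 35.9% in double cKO and 4.81% (2.65 to 7.94) in Np95 cKO, and Nptx1, a neuronal pentraxin, at 35.5% (28.9 to 42.6) and 11.9% (7.99 to 16.8). Tufm, a mitochondrial elongation factor, was at 21.0% (15.4 to 27.5) in double cKO and 5.17% (1.92 to 10.9) in Dnmt1 cKO. The olfactory receptor gene Olfr1189 was at 19.6% (15.6 to 24.0) and 48.0% (41.0 to 55.1) in the same libraries.

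The single knockouts were compared because NP95 acts upstream of DNMT1 in maintenance. Dnmt1 cKO cells had more methylation than Np95 cKO cells by a mean of 7.51 points (SD over rows 9.01, median 5.84), with 86.3% of rows higher and 13.4% lower. By the size rule 1089 rows were higher and 43 lower in Dnmt1 cKO, where simulated rows of equal level in both libraries gave 72 higher and 72 lower. That simulation also drew independent calls, so its counts may be too low. Fisher's exact test between the libraries put 8217 higher and 183 lower. The 5 rows highest in Dnmt1 cKO relative to Np95 cKO were Tas2r117, a bitter taste receptor gene, Ighv3-3, Cox11, Mir103-1 and Gm9920, on 11 to 27 calls in Dnmt1 cKO. Those lowest were Gm4528, LOC100862645, Gm20031, Ttf1 and Pramel7, on 10 to 31 calls in Np95 cKO. Among deep and even rows, BC006965 was at 54.5% (48.0 to 60.9) in Dnmt1 cKO and 18.7% (14.5 to 23.6) in Np95 cKO, and Cyp4f40, a cytochrome P450 gene, at 46.4% (37.4 to 55.5) and 16.7% (11.5 to 22.9). Ibsp, which encodes bone sialoprotein, went the other way, with 13.2% (7.41 to 21.2) in Dnmt1 cKO and 28.1% (21.5 to 35.6) in Np95 cKO.

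TKO cells showed what the assay read without DNA methyltransferases. Of rows, 97.9% lay under 10% in TKO, against 10.4% in Dnmt1 wt, 43.7% in Np95 cKO, 28.4% in Dnmt1 cKO and 33.8% in double cKO. Among rows with at least 50% in Dnmt1 wt, the highest in TKO were Klra3, a natural killer cell receptor gene, at 80% (8 of 10 calls), LOC100048613 at 42.9% on 14 calls, Olfr512 at 42% on 50 calls (28.2 to 56.8), Vmn2r13 at 40% on 10 calls and Mir107 at 35% on 20 calls. Klra3 was at 88.5% (81.7 to 93.4) in Dnmt1 wt and 4.17% (1.15 to 10.3) in Np95 cKO.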

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

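The test of depth share below was chosen after the result was seen. Among rows with at least 100 calls in all 5 libraries, 4 were at least 25 points above Dnmt1 wt in a conditional knockout while another conditional knockout lay below it. With 1 library per group these differences between genotypes were not tested. E2f4, a cell cycle transcription factor, was 31.4 points above the control in Dnmt1 cKO (44.0% on 141 calls, against 12.5% on 543) and at 3.49% in double cKO. Gm11599 was 33.6 points above it in double cKO (44.9% on 167 calls, against 11.3% on 964) and at 4.54% in Np95 cKO. Midn, which encodes midnolin, was 27.9 points above it in double cKO (29.4% on 428 calls, against 1.51% on 863) and at 1.16% in Dnmt1 cKO. Tcta was 26.6 points above it in double cKO (46.5% on 228 calls, against 19.9% on 613) and at 5.98% in Np95 cKO. In Dnmt1 cKO Tcta also lay above the control, at 36.8% on 106 calls, as did Midn in Np95 cKO, at 6.64% on 1386 calls. E2f4 and Gm11599 lay below the control in the other conditional knockouts.

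Rises of at least 25 points were 77 over the 3 conditional knockouts, against 17594, 16266 and 16909 falls in Np95 cKO, Dnmt1 cKO and double cKO. Counting error at low depth was looked at first: 72 of the 77 rises (93.5%) had 95% intervals in control and knockout that did not overlap. This decides little, because the rows were picked for a difference of at least 25 points. The intervals also treat calls as independent. A second candidate explanation is that a different set of MspI fragments was covered, so that the row averaged other cytosines. In 75 of the 77 rises (97.4%) the row's depth share was at most 0.5 of that in the control, against 3.17% of all rows, which is consistent with lost coverage of unmethylated fragments. A gain of methylation in single genes remains open, since the cytosines behind each row are not analysed here.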

How the results depend on the processing

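The alternatives with even depth, deep rows, depth matching and 1 row per imprinted cluster were chosen after the data were seen. Of 178 values recomputed, 80 kept within their counting interval, within 1.5 times the count or on the same side of the random range, and 0 reversed. A level, share or count cannot change sign, so 0 reversals was fixed in advance for these. Most list percentiles kept their side, while most levels and shares moved. Mean levels moved by more than counting error in most settings, but the order Dnmt1 wt, Dnmt1 cKO, double cKO, Np95 cKO, TKO from high to low held in each setting. In that order the levels were 57.0%, 20.9%, 16.9%, 13.3% and 2.82% at 5 calls, 54.2%, 20.1%, 16.3%, 12.8% and 2.75% at 20 calls, 65.6%, 19.4%, 15.4%, 11.9% and 2.22% as medians, 35.5%, 14.8%, 11.8%, 8.71% and 2.32% as pooled calls of rows with at least 10 calls in all 5 libraries, and 53.2%, 19.6%, 16.0%, 12.5% and 2.75% on even rows. On rows of each library alone they were 56.9%, 20.8%, 16.9% and 13.2% before TKO. Beyond the choice of rows and of average, the cause of these shifts was not tested.

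The share of the control level kept in Dnmt1 cKO, double cKO and Np95 cKO was 32.7%, 25.5% and 19.6% after subtracting the TKO level, and 36.2%, 29.3% and 23.6% on even rows, with 4.40% in TKO. With a control minimum of 20% it was 36.1% in Dnmt1 cKO, 29.2% in double cKO and 4.60% in TKO. With a minimum of 80% it was 36.1% in Dnmt1 cKO, 23.4% in Np95 cKO and 4.11% in TKO.

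Counts of changed rows followed the size rule by construction. At 50 points 8569 rows fell in Dnmt1 cKO and 10940 in double cKO. Rises in Np95 cKO were 46 at 10 points, 1 at 50 points, 18 at 5 calls and 5 at 20 calls. In Dnmt1 cKO they were 143, 2, 62 and 25, in double cKO 91 at 10 points and 0 at 50 points, and in TKO 3 at 10 points and 1 at 5 calls. On rows of near-equal depth share, fewer rows were tested: 11076 of 16946 fell in Np95 cKO, 8146 of 12368 in Dnmt1 cKO, 10799 of 16264 in double cKO and 8800 of 11359 in TKO (65.4%, 65.9%, 66.4% and 77.5%, against 68.5%, 63.4%, 65.9% and 72.7% of all rows), and 0, 1 and 0 rose in the conditional knockouts.

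Between double cKO and Np95 cKO the mean difference was 2.65 points as a median, 3.45 on rows of near-equal depth share and 3.26 on deep and even rows, with 3827 higher and 860 lower at 10 points, 7 and 1 at 50 points, and 99 and 11 at near-equal depth share. Between double cKO and Dnmt1 cKO it was −2.40, −3.75 and −3.06, with 1061 higher and 5110 lower at 10 points, 0 and 18 at 50 points, and 20 and 231 at near-equal depth share. Between Dnmt1 cKO and Np95 cKO it was 5.84, 7.37 and 6.32, with 8350 higher and 425 lower at 10 points, 27 and 0 at 50 points, and 353 and 8 at near-equal depth share. The share of rows past 25 points was smaller on rows of near-equal depth share in each pair, for example 2.92% against 4.24% higher in Dnmt1 cKO than in Np95 cKO, so part of these counts goes with uneven depth.

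List percentiles moved across the random range only without matching, which sets a list of low or high starting level against all rows. Unmatched, the imprinted list was at 0.93 in Np95 cKO, germline genes were at 41.3 in double cKO, pluripotency genes at 2.32 in Dnmt1 cKO, markers of other cell types at 2.04, 1.39 and 1.64 in Np95 cKO, Dnmt1 cKO and double cKO, and machinery genes at 1.83 in Np95 cKO and 0.5 in double cKO. Matching in 5 bins, or on level and depth, moved 0 of 42 percentiles across it.

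Leaving out sex chromosomes and the alternatives for repeat families were not run, since the rows carry no chromosomes and no repeat names. No paired analysis was possible because each group has 1 library. Depth limits single rows: a row without methylated calls allows up to 30% at 10 calls and 3% at 100.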

Other observations

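The gene families below and their tests were chosen after the data were seen, as were the tests of coverage, bisulfite conversion, unrecombined cells, call depth and neighbouring rows. Clustered protocadherins, cell adhesion genes whose promoters are chosen at random in single neurons, kept less methylation than rows of the same starting level. Their median (42 rows) was 58.2% in Dnmt1 wt, 8.04% in Np95 cKO, 11.1% in Dnmt1 cKO and 10.3% in double cKO, where matched random lists had 12.1%, 19.5% and 15.8%, and 2, 0 and 0 of 10000 random lists were as low. Vomeronasal type 1 receptors (180 rows), which detect pheromones, were at 83.7% in Dnmt1 wt and 16.7%, 25.6% and 17.3% in the conditional knockouts, and 635, 69 and 0 random lists were as low. The random medians were 17.8%, 27.8% and 21.9%. Olfactory receptors (746 rows) were at 83.3%, then 17.1%, 26.7% and 20.6%, with 515, 178 and 7 random lists as low. These levels lay close to the random medians of 17.6%, 27.7% and 21.8%. Vomeronasal type 2 receptors (144 rows) were at 17.4%, 28.3% and 20%, with 2737, 6342 and 86 as low, so that they lay inside the random range in Np95 cKO and Dnmt1 cKO. In TKO olfactory receptors were at 3.22% and vomeronasal type 1 receptors at 3.38%, with 2 and 67 random lists as high, while vomeronasal type 2 receptors were at 2.33%, with 81 as low.

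Beta-defensins (29 rows), antimicrobial peptide genes, lay above the random range in Np95 cKO and double cKO and inside it in Dnmt1 cKO. They were at 80% in Dnmt1 wt and 23.1%, 28.8% and 26.6% in Np95 cKO, Dnmt1 cKO and double cKO, and 3, 1687 and 50 random lists were as high. MicroRNA rows (297) were at 15.8%, 25.6% and 21.2%, with 1884, 587 and 6 random lists as high. Keratin-associated protein genes (24 rows) were at 22.6%, 35.4% and 26.1%, with 475, 265 and 1241 random lists as high, and in TKO at 4.28%, with 242 as high. Among the 14 families examined, keratin-associated protein, Hox, Rhox, Spink, Zfp, Rpl or Rps, Sox and Fox rows lay inside the random range in each conditional knockout. Families were picked by symbol alone. The Rpl or Rps set (231 rows, 75.5% in Dnmt1 wt) thus takes in names such as Rps15-ps2 and does not stand for ribosomal protein genes. Members of most of these families lie side by side in clusters, so their rows are not independent and the random range is too narrow for them. Whether a family differed more in 1 knockout than in another was not tested.

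Dnmt1 cKO lay above Np95 cKO by 7.51 points on average. On the 12096 rows of near-equal depth share in both libraries the mean difference was 7.37, which argues against uneven total depth as the main cause. Near-equal depth share does not show that the same fragments were covered. Less complete bisulfite conversion in Dnmt1 cKO would raise unmethylated rows most, yet the 1117 rows at 5% or less in Dnmt1 wt differed by 1.19 points. Unrecombined cells in the Dnmt1 cKO culture cannot be told apart from the genotype: with recombined cells at the Np95 cKO level, a share of 17.5% unrecombined cells would give the mean difference and a median difference of 4.90 points over imprinted genes. These differed by 1.91 points, against 4.13 in matched random lists (159 of 10000 as low), but the level of recombined Dnmt1 cKO cells and the start of the Np95 line were not measured, so genotype, cell line and speed of loss by day 6 stay open.

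Imprinted genes were low for their starting level in Dnmt1 cKO and double cKO. With random lists matched on depth as well, the higher of both percentiles was 0.05, with 1 row per imprinted cluster (19 rows) it was 0.01, and on rows with depth share within 1.5-fold of the control (19 rows or more) it was 0.22. These values argue against call depth, neighbouring rows counted more than once and uneven depth share. Whether the same fragments were covered was not tested. No biological explanation was tested. The level of these genes before 4-OHT in the double floxed line was not measured, and a methylated allele beside a bare one was not separated from even partial methylation.

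Some rows kept calls read as methylated in TKO. The row 1700009J07Rik, singled out after its values were seen, was at 22.0% (18.7 to 25.7, 563 calls) in TKO, 57.3% in Dnmt1 wt, 31.4% in Np95 cKO, 34.4% in Dnmt1 cKO and 29.5% in double cKO. Rows of the Y-linked genes Usp9y, Eif2s3y, Zfy1, Ube1y1, Uty and Kdm5d had calls in all 5 libraries, with 169 to 348 calls for Usp9y, which was at 90.4% in Dnmt1 wt, 28.4% in Np95 cKO, 37.9% in Dnmt1 cKO, 27.3% in double cKO and 2.01% in TKO.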
